A study of Homo sapiens with 2 samples.

How the data were processed

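Total RNA of MDA-MB-436, an established human triple-negative breast cancer cell line, was measured on 2 two-colour oligonucleotide arrays. Per the labels, amplified RNA carried amino allyl groups and was coupled to Cy5 or Cy3. Both arrays held RNA of cells infected with an adenovirus carrying IkBaSR in the Cy5 channel. One array held RNA of mock-treated cells in the Cy3 channel (the mock array), and the other held RNA of cells infected with an adenovirus carrying GFP (the GFP array). IkBaSR is the usual name of the super-repressor form of IκBα, the inhibitor that holds NF-κB in the cytoplasm. Each comparison had 1 array, with no replicate and no dye swap.

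The values used were those the authors deposited, 1 log ratio per probe and array, read here as log2. The deposited median was 0 on both arrays, so each column had been centred. The log base, the numerator of the ratio, the scanner, the background correction, the normalization and the reason for empty cells are not given in the sources used here. Spot intensities were not used here, so no filter on dim probes and no check of signal over background could be made. Of 24267 probes, 19633 had a value on the mock array and 18851 on the GFP array, 18154 of them on both. The interquartile limits were -0.18 and 0.19 on the mock array and -0.18 and 0.20 on the GFP array. Normalization to a median of 0 leaves only changes relative to the typical probe.

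The direction of the ratio stayed open. The titles and the design name the control before the IkBaSR cells, which would make the ratio control over IkBaSR. The dyes put the IkBaSR cells in Cy5, and the usual Cy5 over Cy3 would make it IkBaSR over control. Values are therefore given on the positive or negative side of the deposited ratio, with no statement that a transcript was higher in one of the cells. Both arrays have the same dye orientation.

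Gene symbols came from the platform annotation, which can be old. It gave 1 symbol for 13395 probes, none for 10872 and several for 0. Of 12474 symbols, 10076 were current in a RefSeq gene table of assembly GRCh38.p14, 2285 were updated through a unique synonym and 113 were kept as written because no unique match was found. That table served for names only, and no coordinates are given because no genome build is named for the probes. Probes of a gene were averaged over those measured on both arrays. This left 10274 named probes and 9702 genes.

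The comparisons were the ratio on the mock array, the ratio on the GFP array, genes at or past 2-fold on the same side of both arrays, and the mock array value minus the GFP array value. In that difference a dye effect tied to a gene cancels, and so does the IkBaSR RNA if both arrays held the same extract. It then is an indirect comparison of GFP virus and mock cells, again with open direction; with separate extracts it also holds the difference between them. With 1 array per comparison no test was made and no p-value is given. A gene counted as past 2-fold at a log2 ratio of 1 or more in size. Both arrays hold RNA from cells labelled alike, and whether it was the same extract is not given in the sources used here. The overlap and correlation were therefore set beside 100 simulations of 3 unchanged RNAs with independent noise, and beside the overlap of independent lists.

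The analysis covered 27 gene lists, and each list median was placed among the medians of 10000 random lists of the same size drawn from the 9702 genes. Matching on expression level was not possible without intensities. These percentiles describe these arrays and are not p-values. The lists, the comparisons and the rule for naming genes were set before the data were examined. The rule took NFKBIA, the 12 genes at each end by the smaller of the 2 absolute ratios among genes with the same sign, the 4 at each end of each array and the 10 at each end of the difference. For each list it took the 2 lowest and 2 highest members by the mean of the arrays and every member past 2-fold on both. For the NF-κB and interferon lists it also took the 2 members at each end of the difference. Symbols starting with LOC and open reading frames without a symbol were skipped in the rankings but counted in the totals.

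The steps were tested on simulated data with planted changes. Of 50 genes planted at each size among 9702, the step that asks for 2-fold on both arrays recovered 0% at 1.5-fold, 22% at 2-fold, 98% at 4-fold and 100% at 8-fold. It also called 0.779% of 9502 unchanged genes. In the data, 0.454% of genes were past 2-fold on the positive side of both arrays and 0.0618% on the negative side. The simulated noise alone thus gave a larger share of calls than all genes of the data. The recovered and called shares therefore describe the simulated noise only and give no valid rates for these arrays. Among 40 simulated lists of 20 genes, 1 unshifted list lay outside the central 95% of random lists, against 37 of 40 lists shifted by 0.3.

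Alternatives were thresholds of 1.5-fold and 3-fold, centring on the median gene, scaling the arrays to one spread, the probe nearest 0, probes counted singly, Spearman correlation, genes under 2-fold on both arrays, list means and lists without the member farthest from 0. Counts over all probes, named or not, and over every gene with a value on that array were added after the data were seen. Probes without a symbol were left out of the gene counts because nothing names them. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.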

Results

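The data were log2 ratios from 2 arrays of MDA-MB-436 cells. The mock array paired cells carrying the IkBaSR adenovirus with mock cells, and the GFP array paired IkBaSR cells with cells carrying a GFP adenovirus. On the mock array adenovirus infection and IkBaSR thus cannot be told apart, while on the GFP array both RNAs came from infected cells. By its title the series looked for target genes of NF-κB, the transcription factor family that IκBα restrains. The standard deviation of the deposited ratios over probes was 0.405 on the mock array and 0.423 on the GFP array. Values ran from -2.95 to 4.11 and from -3.19 to 3.96. Each value came from 1 array without a replicate, so no value has an error and the number of arrays limits the precision.

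NFKBIA, which encodes IκBα and is itself switched on by NF-κB, had a log2 ratio of 2.24 on the mock array and 2.31 on the GFP array, from 1 probe. If the ratio was control over IkBaSR, a positive value means more transcript in the control cells. If it was IkBaSR over control, it means more in the IkBaSR cells. The place of the NFKBIA probe in the transcript, and so whether it reads the transcript of the vector, is not given in the sources used here. Its value therefore checks neither the labels nor the direction.

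On the mock array, which compared IkBaSR cells with mock cells, the highest ratio of the 9702 genes belonged to BIRC3, an inhibitor of apoptosis, at 3.26. VNN2, a pantetheinase, followed at 2.84, then TNFAIP3, the ubiquitin-editing enzyme A20 that dampens NF-κB signalling, at 2.82, and ESM1, a secreted proteoglycan, at 2.75. A single probe of CXCL8 read 4.11, but the mean over the probes of that gene was 1.97. At the other end lay NGFR, the low-affinity neurotrophin receptor, at -2.12, AQP11 at -1.93, GTF2A1 at -1.88 and KCNJ4, a potassium channel, at -1.86. On the GFP array AQP11 was at -0.31, GTF2A1 at -0.87 and KCNJ4 at -0.01. Of 9702 genes, 104 were past 2-fold on the positive side and 108 on the negative side. With every gene that had a value on this array, the positive count was 204 and the negative count 126.

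On the GFP array, which compared IkBaSR cells with cells carrying another adenovirus, BIRC3 was again highest of the 9702 genes, at 3.77. The monocyte chemoattractant CCL2 was at 3.47, TNIP3, which binds A20, at 3.0, and TNFAIP3 at 2.91. The same CXCL8 probe read 3.96, but the mean for CXCL8 was 1.75. The lowest genes were TBX19, a T-box transcription factor, at -2.34, HEXA, a lysosomal hexosaminidase subunit, at -1.81, the serotonin receptor HTR1D at -1.62 and the receptor GPR119 at -1.53. On the mock array HEXA was at -0.16 and HTR1D at -0.11. Past 2-fold lay 108 genes on the positive side and 113 on the negative side. With every gene that had a value on this array, the positive count was 219 and the negative count 116.

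Past 2-fold on the same side of both arrays lay 44 genes on the positive side and 6 on the negative side. The size of this imbalance depended on the setting, with 129 and 105 genes at 1.5-fold and 14 and 1 at 3-fold. Over all probes, named or not, the counts were 59 and 20, and among probes without a symbol 13 and 12. The positive count was the larger at each of these settings. Chemokines and regulators of NF-κB were among the highest. BIRC3 was at 3.26 and 3.77 on the mock and GFP arrays and TNFAIP3 at 2.82 and 2.91. CCL2 stood at 2.65 and 3.47, RELB, an NF-κB subunit, at 2.60 and 2.68, and the neutrophil chemokine CXCL1 at 2.31 and 2.42. TNIP3 stood at 2.04 and 3.0, ESM1 at 2.75 and 2.36, and SERPINB2, plasminogen activator inhibitor 2, at 1.98 and 2.08. The chemokines CXCL3 and CCL20 were at 1.77 and 1.87 and at 1.62 and 1.87. KLRC1, which encodes the receptor NKG2A, was at 1.93 and 1.77.

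CXCL8, the chemokine interleukin 8, averaged 1.97 and 1.75, but its probes disagreed. One CXCL8 probe read 4.11 and 3.96, another -0.16 and -0.45, and the last had only a GFP array value of 0.42.

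The 6 genes past 2-fold on the negative side of both arrays were TBX19, NGFR, CDKN1C, BARX2, NPR3 and JUND. TBX19 stood at -1.72 and -2.34, NGFR at -2.12 and -1.28, and CDKN1C, an inhibitor of cyclin-dependent kinases, at -1.59 and -1.19. BARX2, a homeobox gene, was at -1.13 and -1.38, the natriuretic peptide receptor NPR3 at -1.05 and -1.05, and the AP-1 subunit JUND at -1.01 and -1.26. The next by the smaller ratio were DRD2 at -1.10 and -0.95, AZU1 at -0.95 and -1.21, S100A1 at -1.26 and -0.94, ESPN at -1.15 and -0.91, SEMA4G at -1.53 and -0.90 and KLK10 at -1.11 and -0.90.

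**Figure D1:**
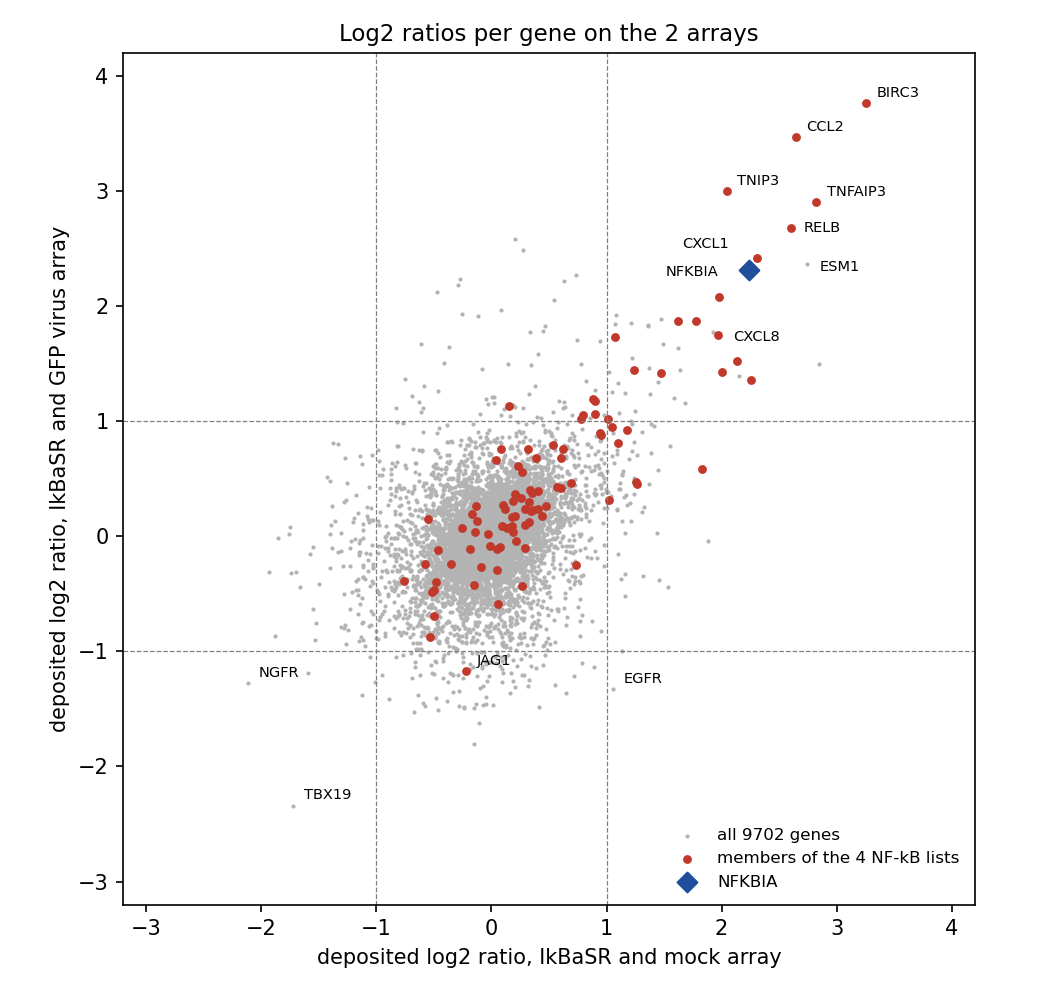
Deposited log2 ratio of each of 9702 genes on the mock array (horizontal axis) against the GFP array (vertical axis), with members of the 4 NF-κB lists in red, NFKBIA as a blue diamond and dashed lines at 2-fold. In the upper right corner, past 2-fold on both arrays, lie 44 genes led by BIRC3, and in the lower left corner lie 6, among them TBX19 and NGFR.

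Independent lists of these sizes would share 1.16 positive and 1.26 negative genes. Simulated unchanged RNAs, which share the noise of one RNA, gave a mean of 41.1 positive genes (25 to 61) and 42.3 negative genes (27 to 59). Across genes, which are not independent replicates, Pearson's r between the arrays was 0.400 and Spearman's rho 0.387, with a simulated mean r of 0.502 (0.478 to 0.540). The covariance was 0.0529 beside a simulated mean of 0.0802 (0.0742 to 0.0908). The simulation assigns all noise to the RNAs and overshot the observed correlation, covariance and negative overlap, so it gives no valid value for unchanged cells. Part of the overlap may come from the shared IkBaSR RNA, and no excess is read as a shared effect.

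Of 96 measured members of the 4 NF-κB lists, 17 were past 2-fold on the positive side of both arrays, 17.7% (exact 95% interval 10.7 to 26.8, counting error only). The share was 1 of 403 in the other lists, 0.248% (0.00628 to 1.37), the gene being GADD45A at 1.25 and 1.09, and 25 of 9202 genes outside every list, 0.272% (0.176 to 0.401). NFKBIA was left out of these shares. On the negative side the counts were 0 of 96, 1 of 403 and 5 of 9202.

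Among 20 measured pathway members and feedback regulators of NF-κB, 13 were positive on both arrays and 3 negative on both. TNFAIP3, RELB, TNIP3 and NFKBIE, the IκBε inhibitor, were past 2-fold on both, with NFKBIE at 2.25 and 1.36. The kinase MAP3K8 was at -0.57 and -0.24 and MAP3K14, the NF-κB inducing kinase, at -0.09 and -0.26. The list median was 0.25 on the mock array and 0.29 on the GFP array, at percentile 100 of random lists on both.

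Of 26 cytokines and chemokines under NF-κB control, 17 were positive on both arrays and 4 negative on both. Past 2-fold on both were 7, namely CCL2, CXCL1, CXCL3, CCL20, CXCL8, IL6 at 1.24 and 1.45 and IL1B at 2.14 and 1.53. The lowest were CSF3, the granulocyte colony-stimulating factor, at -0.53 and -0.88 and CX3CL1 at -0.50 and -0.69. The median was 0.68 and 0.76, at percentile 100 on both arrays.

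Of 16 survival genes, 11 were positive and 2 negative on both arrays, and BIRC3 and SERPINB2 were past 2-fold on both. BCL2 was at -0.51 and -0.49 and the ferritin heavy chain gene FTH1 at -0.48 and -0.40. The median was 0.23 at percentile 99.8 on the mock array and 0.32 at percentile 99.97 on the GFP array. Of 34 adhesion, receptor and matrix genes, 26 were positive and 5 negative on both arrays. Past 2-fold on both were PTGS2, which encodes cyclooxygenase 2, at 2.00 and 1.43, the pentraxin PTX3 at 1.48 and 1.42, the adhesion molecule ICAM1 at 1.02 and 1.02 and the receptor TNFRSF9 at 1.07 and 1.73. The Notch ligand JAG1 was at -0.22 and -1.17 and NNMT at -0.76 and -0.39. The median was 0.34 and 0.28, at percentile 100 on both arrays.

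**Figure D2:**
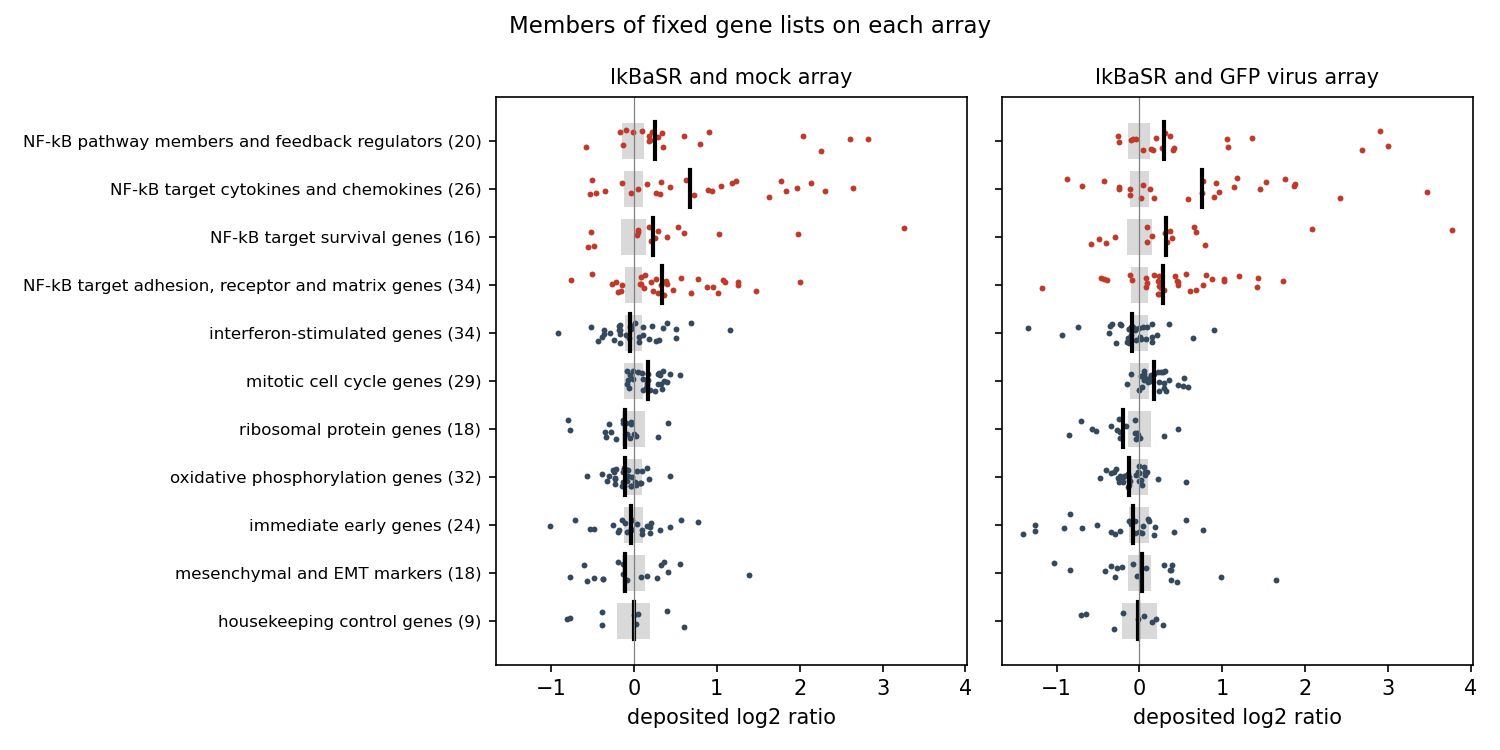
Log2 ratio (horizontal axis) of each measured member (points) of 11 lists (rows, with the number of measured members) on the mock array (left) and the GFP array (right), with the list median as a black bar and the central 95% of medians of random lists in grey. The medians of the 4 NF-κB lists and of the mitotic list lie to the right of the grey band on both arrays.

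The mitotic list was the only other list above the central 95% of random lists on both arrays. Of 29 measured mitotic genes, 21 were positive on both and 2 negative on both, with none past 2-fold on both. DLGAP5, a spindle protein, was at 0.55 and 0.52, the kinase NEK2 at 0.31 and 0.58, AURKB at -0.08 and -0.11 and the proliferation marker MKI67 at -0.01 and -0.15. The median was 0.17 on both arrays, at percentiles 99.8 and 99.9.

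Outside the central 95% on the GFP array alone lay 3 lists, all on the negative side. The ribosomal protein genes had a median of -0.11 (percentile 6.21) on the mock array and -0.20 (percentile 0.42) on the GFP array, with RPS2 at -0.79 and -0.85, RPLP0 at -0.77 and -0.71 and RPS19 at 0.42 and 0.46. Of 32 oxidative phosphorylation genes, 21 were negative on both arrays and 6 positive on both, with medians of -0.10 (percentile 3.71) and -0.12 (percentile 1.31). The luminal breast markers, a check for another cell type, had medians of -0.01 (percentile 47.8) and -0.22 (percentile 2.00). Each of these calls was lost under 1 alternative. The GFP array percentile was 5.39 for the ribosomal list with the probe nearest 0, 6.25 for the oxidative phosphorylation list by its mean and 4.55 for the luminal list without the member farthest from 0.

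The other 19 lists lay inside the central 95% on both arrays, with medians between -0.16 and 0.12 and percentiles between 4.25 and 91.8. They were the interferon-stimulated, DNA replication, histone, p53 target, apoptosis, immediate early, heat shock, unfolded protein response, cholesterol synthesis, hypoxia, epithelial, mesenchymal, basal breast, Notch, NRF2 target, proteasome, leukocyte, endothelial and housekeeping lists. Single members still lay far out. The immediate early gene ZFP36, which encodes tristetraprolin, was at -0.48 and -1.40 and CCN1 at 0.78 and 0.56. The mesenchymal regulator SNAI1 was at -0.77 and -1.03 and the collagen crosslinking enzyme LOX at 1.39 and 0.98. The NRF2 target TXNRD1, a thioredoxin reductase, was at 1.09 and 0.72 and the ferritin light chain gene FTL at -0.67 and -0.65. The Notch ligand DLL1 was at 0.95 and 0.84. Of the housekeeping genes, GAPDH was at -0.81 and -0.65 and POLR2A at 0.61 and 0.15. If the members of each list varied independently, like randomly drawn genes, 1.35 of 27 lists would lie outside the central 95% on an array. Members of a list need not vary independently, so this number is no chance level for these lists. There were 5 above and 0 below on the mock array, and 5 above and 3 below on the GFP array.

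The mock array value minus the GFP array value gave the indirect comparison of GFP virus and mock cells, if both arrays held the same IkBaSR extract. EGFR, the epidermal growth factor receptor, was highest at 2.39, followed by CPE, carboxypeptidase E, at 2.13, the alkaline phosphatase ALPP at 2.03, C2CD2 at 2.01 and the copper transporter ATP7B at 1.97. OCSTAMP, PLA2G12A, TCTA, ZNF501 and PLA2G10 lay between 1.93 and 1.85. Lowest were EVI5 at -2.59, the histone gene H2BC17 at -2.51, KLF16 at -2.47, PLAAT1 at -2.38 and INE1 at -2.28. VNN1, OR8A1, SOX14, FEZ1 and ZNF300 lay between -2.21 and -2.12. Past 2-fold were 165 genes on the positive side and 186 on the negative side.

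None of the 27 lists lay outside the central 95% in this difference, where medians ran from -0.09 to 0.11. Of 34 interferon-stimulated genes, which respond to infection by many viruses, 16 were positive and 18 negative in this difference. Of these, 3 were past 2-fold on the positive side and 0 on the negative side. TRIM22 was at 1.49, IFIT5 at 1.44 and IFIT1 at 1.06, against IFITM1 at -0.92 and USP18 at -0.53. The interferon list had a median of -0.03 at percentile 21.5 and a mean of 0.10 at percentile 93.0. It had medians of -0.04 (percentile 22.8) and -0.09 (percentile 4.25) on the mock and GFP arrays. In the NF-κB lists the difference was highest for CXCL6 at 1.25, EDN1 at 0.98, JAG1 at 0.95 and NFKBIE at 0.89, and lowest for CCL5 at -0.98, TNIP3 at -0.95 and CCL2 at -0.83. Other extremes within these lists were MMP1 at 0.81, CCND1 at 0.71, PIM1 at 0.64, IKBKE at 0.39, RIPK2 at -0.36, BCL2A1 at -0.62, TNFRSF9 at -0.66, TLR2 at -0.68 and XIAP at -0.70. The difference carries the noise of both arrays and has no replicate. For 505 genes with several probes on both arrays, the median range between probes of a gene was 0.258 on the mock array and 0.289 on the GFP array.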

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

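The tests on the direction of the ratio, on dye bias and on the interferon response were chosen after the results were seen. The counts of probes without a symbol, and the simulations for them and for genes on opposite sides, were also added then.

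EGFR lay past 2-fold on opposite sides of the arrays, at 1.06 on the mock array and -1.33 on the GFP array, a difference of 2.39. It was the only gene of 9702 to do so. Independent lists would give 1.21 genes with the mock array positive and 1.20 with it negative. Simulated unchanged RNAs that share one RNA gave means of 0.30 (0 to 2) and 0.22 (0 to 2), with all noise assigned to the RNAs. That simulation overshot the observed correlation, so these means may be too low and give no valid value for unchanged cells. The difference was not tested, since each array stands alone.

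Probes that carry no gene symbol were outside the gene comparisons, yet some held large values. Of 7880 such probes measured on both arrays, 13 were past 2-fold on the positive side of both and 12 on the negative side. Independent lists would share 0.704 and 1.25. Simulated unchanged RNAs that share one RNA gave means of 40.03 (23 to 56) and 38.9 (25 to 57). That simulation assigns all noise to the RNAs and so overstates the overlap, while independent lists leave out the shared RNA, so neither value decides whether these probes share an effect. The strongest on each side were H200020130 at -2.95 and -3.19 and H200000203 at 2.18 and 2.32.

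NF-κB genes crowded the positive side of both arrays. A dye bias that falls on genes alike, whatever their function and spot intensity, is argued against by the share past 2-fold on both. That share was 17.7% in the NF-κB lists beside 0.248% in the other lists, with intervals that do not overlap. The intervals hold counting error only and treat genes as independent. The lists were not matched on spot intensity, so a dye bias tied to intensity is not covered. If IkBaSR lowered NF-κB targets, the ratio may be control over IkBaSR, but the list medians, at percentile 99.83 or above on both arrays, are the pattern itself and do not test the direction. NFKBIA, at 2.24 or more on both arrays, could be positive under either ratio, from the cell's own gene or from the vector, and decides nothing. IkBaSR over control would need NF-κB lists that were raised in the IkBaSR cells, against the action of a repressor of NF-κB. No value tests whether the repressor worked, so the direction stays open. A dye effect specific to these genes or tied to spot intensity stays open too.

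In the difference between the arrays, 165 and 186 genes lay past 2-fold. An interferon response to the GFP virus stays open, since the list median lay at percentile 21.5 of random lists and the mean at percentile 93.0, over 16 positive and 18 negative members. Noise of single probes may account for some of these genes and cannot be told apart from real differences. For 42 genes with 1 probe past 2-fold, the other probes had a median signed difference of -0.00583 (95% bootstrap interval -0.131 to 0.132), and in 21 they had the same sign. A median near 0 is what noise of single probes would give, and the interval lay below the limit set for it beforehand. The same measure on the mean of both arrays gave -0.0111 (-0.248 to 0.233) over 8 genes, with the same sign in 3. For these 8 genes the other probes thus did not follow the far probe either. So few genes make this comparison weak, and the test cannot tell noise from real differences. The genes named at the ends of the difference had 1 probe each.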

How the results depend on the processing

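Counts over all probes and over every gene with a value on an array were chosen after the data were seen. Each array stood alone, so no array could be left out. No paired analysis was possible because each comparison had 1 array. Centring on the median gene, scaling to one spread and counting probes singly kept every count within 1.5 times its reported value. The gene medians were already -0.0036 on the mock array and -0.0039 on the GFP array, and the scaling factors were 1.011 and 0.989. Centring and scaling therefore had little room to change any value. NFKBIA stayed between 2.24 and 2.32 under centring and scaling.

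At 1.5-fold the mock array had 367 positive and 434 negative genes, the GFP array 409 and 506, both arrays 129 and 105 and the difference 548 and 587. At 3-fold these were 24 and 11, 41 and 3, 14 and 1, and 18 and 39. The looser or stricter threshold itself gives these counts. Over all probes, named or not, the mock array had 167 and 209, the GFP array 219 and 243 and the difference 323 and 402, with 59 positive and 20 negative probes on both arrays. More features enter these counts by construction. With every gene that had a value on that array, 10381 on the mock array and 10007 on the GFP array in place of 9702, the positive counts were 204 and 219 and the negative counts 126 and 116. The number of genes does not account for this one-sided rise, and its cause was not tested.

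The correlation was 0.335 over genes under 2-fold on both arrays, which leaves out the far genes. The means of the NF-κB lists moved away from their medians, to 0.65 and 0.68 on the mock and GFP arrays for the NF-κB pathway, 0.46 and 0.50 for survival genes, 0.43 and 0.40 for adhesion, receptor and matrix genes and 0.79 for cytokines on the mock array, while the cytokine mean of 0.74 on the GFP array lay below the median of 0.76. The interferon list mean in the difference was 0.10 (percentile 93.0), against a median of -0.03 (percentile 21.5). With the probe nearest 0 the cytokine median was 0.53 and 0.67, and CXCL8 turned from positive to -0.16 and -0.45, because its probes disagree. The cause of the other changes was not tested. Over the alternatives run on lists, the lowest percentile of any NF-κB list on either array was 99.5.

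Of 324 list results, 3 left the outer 5% of random lists under an alternative and 4 entered it. The 4 were, by list means, immediate early genes at -0.24 on the GFP array and 0.21 in the difference, and basal breast markers at -0.31 and 0.25. Among values of single genes and other lists, 1760 of 1785 stayed the same, 23 moved and 2 reversed. That tally is a weak check, since centring gave 573 of these values and scaling 507, with little room to change. The probe nearest 0 cannot change a gene with 1 probe. By list means, 17 of the other list values moved and 49 stayed the same. Among the counts, the correlation, NFKBIA and the NF-κB and interferon lists, 36 of 127 results moved. Of these, 8 moved at 1.5-fold and 8 at 3-fold. Signal over background could not be examined, so which ratios rest on dim spots is unknown.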

Other observations

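Apart from NFKBIA, VNN2 and ZEB1, the genes below were named after their values were seen, and so were the counts of probes measured on a single array.

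Of the 44 genes past 2-fold on the positive side of both arrays, 26 were in no list, NFKBIA among them. IRAK2, a kinase of interleukin 1 and Toll-like receptor signalling, was at 1.37 and 1.47 on the mock and GFP arrays, CH25H, which makes 25-hydroxycholesterol, at 1.64 and 1.44, and OLR1, a receptor for oxidised low-density lipoprotein, at 1.36 and 1.84. VNN2 was at 2.84 and 1.5. The growth factor EREG, a ligand of EGFR, was at 1.10 and 1.33, and ALDH1A3, a retinaldehyde dehydrogenase, at 1.38 and 1.24. RRAD, a small GTPase, was at 1.48 and 1.89, MYBL1, a transcription factor, at 1.21 and 1.86, the phosphatase PPM1H at 1.03 and 1.43 and the liver arginase ARG1 at 1.59 and 1.21. Each had 1 probe.

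ZEB1, a repressor of epithelial genes, was at -0.37 on the mock array and 1.65 on the GFP array. No test of that difference was possible.

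Probes with a value on 1 array alone were more often far from 0. Of 777 named probes measured on the mock array alone, 133 were past 2-fold there, 17.1%, and of 351 measured on the GFP array alone, 125 were, 35.6%. Among named probes measured on both, the shares were 2.25% and 2.45%. The reason for the empty cells is not given in the sources used here.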
